A study of Mus musculus with 12 samples.

How the data were processed

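Gene expression was measured by RNA sequencing in 12 libraries of mouse CD4+ T cells, 3 for each combination of genotype (control or Orai1, Orai2 and Orai3 triple knockout, TKO) and time (6 h or 24 h). Per the labels' protocols, naive CD4+ CD25- cells were enriched magnetically from spleen and lymph nodes, cultured with antibodies to CD3 and CD28 under conditions that favour pathogenic Th17 cells, and sequenced as stranded mRNA libraries in paired reads of 50 bases on a NovaSeq instrument. The labels give the cells as female and name 1 date for all libraries, so no batch could be set against a group. Per the labels, cells of 4 biological replicates per genotype were pooled and divided into 3 technical replicates, and the p-values measure the spread between those.

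Per the submitters' processing notes, the tools were bcl2fastq 2.19.1.403, STAR 2.7.9a and Partek and the genome builds GRCm39 and mm10, with no role given for any of them here. The annotation, the strand setting and the counting rule are not given in the sources used here. The deposited table of gene counts holds expected counts, since 43.6% of its values were not whole numbers within 1e-06. Such estimates can divide reads between genes, so values of near-identical copies such as Hba-a1 and Hba-a2 are uncertain. It lists 24040 genes, each with a total of at least 10 over the 12 libraries, 637 of them without a symbol. The authors also deposited CPM plus 0.0001 for the same libraries, and these values equalled CPM computed from the counts within a relative difference of 1.9e-05. The tests had been planned for whole counts, and the expected counts were rounded to whole numbers first.

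The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups (17184 genes), library sizes were scaled by TMM, and 1 quasi-likelihood model (glmQLFit, robust set to false) was fitted to all 12 libraries with a mean per group. TKO was compared with control at each time, 24 h with 6 h in each genotype, and the interaction of genotype and time was tested, all two-sided. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the fold change at least 1.5. CPM in the text are per library total without TMM factors, whereas fold changes are TMM scaled. Where a group held no counts, the fold is given against a floor of 3 counts over the group, which covers counting error only. Camera (limma 3.58.1, preset correlation 0.01) tested 35 gene lists with 832 of 889 entries tested, covering T cell programs, metabolism, stress, the cell cycle and markers of other cell types, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with the correlation estimated from the data, and fry was run as an alternative. The design, the gene lists, the thresholds and the rule for named genes were chosen before the data were examined.

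The rule named 22 genes of calcium entry, Th17 cytokines and activation in the genotype comparisons. It added the 6 largest called changes each way at 6 h and 24 h and the 4 largest each way for the time changes and the interaction, with at least 10 CPM in the higher group and no overlap between libraries, which 10% of genes without a change would show by chance with 3 libraries against 3. Predicted genes and receptor segments were left out there. For each list described it took the called members with the largest changes in that order and the most abundant member. Members at the floor, or whose value moved by over 1.5 times when 1 library was left out, are given as CPM or left out. Some genes that meet the rule are not reported here. Genes outside the rule are said to be named after their values were seen.

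The fit was tested on simulated counts with 200 changed genes. For the comparison at 6 h, 17007 genes were tested and 41 of 73 genes changed by 1.5-fold, 63 of 63 changed by 2-fold and 64 of 64 changed by 4-fold were called, with 4 unchanged genes called. The simulation kept all other genes equal between groups and gave every gene the same spread beyond counting noise. In the real data 53.4% of genes were called at 6 h, so the simulation does not test the scaling or false calls under such wide change. Library totals were 27525004 to 37555042 counts. No libraries of a group held identical values, and pairs of replicates differed by more than counting noise (chi-square per degree of freedom 2.82 to 29.8). Alternatives were the DESeq2 1.42.0 size factors and library size alone, no filter and a filter of 10 CPM in 3 libraries. Other tools were DESeq2, limma voom and limma on the authors' CPM. For the last, 1 or 0.0001 was added here to the deposited values, which already held 0.0001 (called CPM plus 1 and plus 0.0001). Further alternatives were a replicate block, other fold minimums and glmTreat, leaving out each library, and fitting only the 6 libraries compared. Leaving out genes of the sex chromosomes, of other cell types and of skin was added after the data were seen. Coordinates were taken from the table, and no sequence was used here.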

Results

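RNA sequencing of bulk cultures measured transcripts of mouse naive CD4+ T cells that had been isolated from spleen and lymph nodes and activated through CD3 and CD28. The medium held IL-6, IL-23 and IL-1β with antibodies against IL-4 and IFN-γ, a mixture that drives differentiation into T helper 17 (Th17) cells of the inflammatory kind called pathogenic. Wild-type control cells were set beside triple knockout (TKO) cells, labelled as knockouts of Orai1, Orai2 and Orai3, which encode the pore subunits of the calcium channels that open when the endoplasmic reticulum loses its calcium. Cells were harvested at 6 h and at 24 h, which gave 4 groups of 3 libraries. Per the labels, cells of 4 biological replicates per genotype were pooled and then divided into 3 technical replicates per condition, so every p-value given here measures technical spread and not the spread between mice. The libraries held between 27525004 and 37555042 counts each. Between 20729 and 22677 genes had a count in a library. Levels are mean ± SD of 3 libraries in CPM, counts relative to the library total. Changes are log2 fold changes ± an approximate SE, the size of the change divided by the square root of edgeR's F statistic. A gene rose or fell where its adjusted p was under 0.05 and its fold change at least 1.5.

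The targeted genes were read in each library first. Orai1 (ENSMUSG00000049686, protein coding, chromosome 5, 123153137 to 123168519, plus strand) lay at 113, 95.6 and 106 CPM in control replicates 1, 2 and 3 at 6 h and at 4.95, 4.34 and 3.8 CPM in the TKO replicates. At 24 h the values were 55, 47.8 and 48.8 CPM in controls and 2.77, 2.31 and 3.78 CPM in TKO. The log2 fold change of Orai1 was -4.81 ± 0.12 at 6 h and -4.17 ± 0.13 at 24 h (adjusted p = 1.44e-13 and 1.39e-12, edgeR). Transcript counts of the other targeted genes did not fall. Orai2 (ENSMUSG00000039747, protein coding, chromosome 5, 136176313 to 136199567, minus strand) lay at 14.8, 15.2 and 15.2 CPM in controls and 110, 116 and 128 CPM in TKO at 6 h, and at 25.6, 27.4 and 34.5 and 151, 148 and 175 CPM at 24 h. It rose by 2.74 ± 0.099 and 2.37 ± 0.095 on the log2 scale. Orai3 (ENSMUSG00000043964, protein coding, chromosome 7, 127368987 to 127374322, plus strand) lay at 8.37, 8.46 and 9.87 CPM in controls and 10, 10.3 and 10.4 CPM in TKO at 6 h, and at 8.78, 7.52 and 9.49 and 12.9, 13.5 and 13.5 CPM at 24 h. Its log2 fold change was -0.03 ± 0.1 (adjusted p = 0.834, edgeR) at 6 h and 0.56 ± 0.10 at 24 h. That value was under the fold minimum, which it passed without control replicate 3 at 24 h (0.63) and with library size scaling (0.63). Coordinates are as deposited, and the submitters' notes name both GRCm39 and mm10. Of 23313 gene identifiers shared with a GENCODE annotation of mm10, 496 had the same start there. The exons removed from each gene are not given in the sources used here, so a count over a whole gene checks the Orai1 allele but leaves the Orai2 and Orai3 alleles unchecked. Xist, the RNA that coats the inactive X chromosome, also separated the genotypes, at 615 ± 51.1 and 863 ± 80.8 CPM in controls against 0.416 ± 0.235 and 0.47 ± 0.0715 CPM in TKO. All cells are labelled female. The summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 148 ± 6.7 and 166 ± 4.76 CPM in controls and 367 ± 33.9 and 476 ± 16.4 CPM in TKO at 6 h and 24 h. Over all 15 Y chromosome genes of the table the sum was 366 ± 16.6 and 295 ± 2.87 CPM in controls and 495 ± 45.3 and 571 ± 21.6 CPM in TKO.

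**Figure D1:**
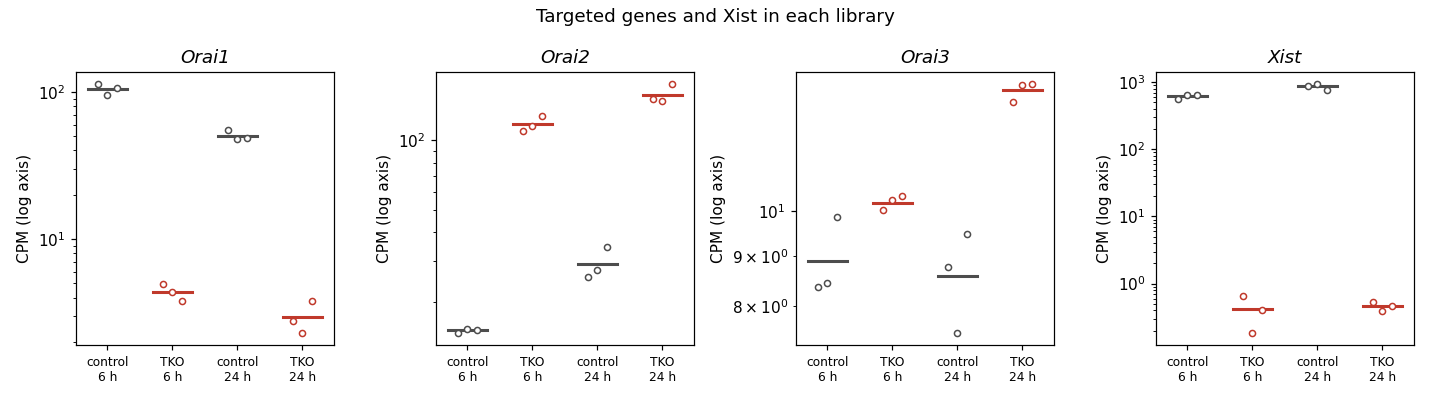
CPM of Orai1, Orai2, Orai3 and Xist in each of the 12 libraries (points, log axis) with the group mean (bar) in control and TKO cells at 6 h and 24 h. Orai1 lay at 105 and 50.5 CPM in controls against 4.36 and 2.95 CPM in TKO, and Orai2 at 15.1 and 29.2 CPM against 118 and 158 CPM.

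The comparison at 6 h asked how the Orai knockout changes the early response to activation. Il2, the T cell growth factor and a target of the calcium-dependent factor NFAT, fell from 423 ± 12.1 to 5.74 ± 1.07 CPM (log2 fold change -6.43 ± 0.14, adjusted p = 5.19e-14, edgeR). Xcl1, a chemokine, fell (-7.35 ± 0.21). Crtam and Tnfsf14, which encode surface proteins of activated T cells, fell (-6.18 ± 0.12 and -5.33 ± 0.10). In all, 4982 of 17184 genes rose in TKO and 4195 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment).

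In the list of T cell receptor and NFAT early response genes, 20 of 34 fell and 5 rose (camera adjusted p = 2.02e-06, adjusted p = 0.13 with an estimated correlation). Il3, another T cell cytokine, fell from 2.95 ± 0.626 to 0.0694 ± 0.0602 CPM. Irf4, the most abundant member, stood at 2520 ± 48.1 and 2690 ± 127 CPM. Egr2 fell (-1.67 ± 0.082). Nr4a1 had a log2 fold change of 0.56 ± 0.065, under the fold minimum, which it passed without control replicate 1 at 6 h (0.62), control replicate 2 at 6 h (0.59), TKO replicate 3 at 6 h (0.60) and TKO replicate 1 at 24 h (0.59). With library size scaling Nr4a1 stood at 0.79. Genes of naive and resting T cells moved the other way, with 23 of 28 higher and 2 lower (camera adjusted p = 7.4e-13). They included Ypel3 (4.85 ± 0.14) and S1pr1 (4.72 ± 0.13), which lets T cells leave lymph nodes. Another was Il7r (4.06 ± 0.17), the receptor for the survival cytokine IL-7. Of the trafficking and adhesion genes, 19 of 26 rose and 3 fell (camera adjusted p = 1.95e-08), led by Ccr2 (6.37 ± 0.15) and Itgb3 (5.40 ± 0.22). Of the Treg markers 8 of 13 rose and 1 fell (camera adjusted p = 0.0027), with Nt5e at 4.63 ± 0.14 and Ikzf4 at 2.86 ± 0.12. Of the genes of calcium entry itself, 12 of 34 rose and 6 fell (camera adjusted p = 0.265). Stim1, the calcium sensor of the endoplasmic reticulum, rose from 20.6 ± 0.756 to 82.5 ± 4.51 CPM (1.77 ± 0.076). Stim2 had a log2 fold change of -0.24 ± 0.042, under the fold minimum.

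Myc, a driver of cell growth, fell from 1210 ± 23.5 to 176 ± 6.26 CPM (-3.02 ± 0.064). In the Myc and ribosome biogenesis list, 34 of 36 genes fell (camera adjusted p = 4.39e-34), among them Ncl (-2.33 ± 0.072), Npm1 (-2.27 ± 0.079) and Srm (-2.27 ± 0.072). The member that rose was Odc1, a polyamine synthesis enzyme, from 735 ± 33.8 to 2240 ± 109 CPM, a gene named after its values were seen. Cytosolic ribosomal proteins were lower for 28 of 39 and higher for 0 (camera adjusted p = 4.5e-08, adjusted p = 0.304 with an estimated correlation), with Rpl37 at -1.25 ± 0.14 and Rpl10a at -1.22 ± 0.073. Nucleotide synthesis genes fell for 20 of 24 (camera adjusted p = 4.25e-10, adjusted p = 0.184 with an estimated correlation), with Dctpp1 at -2.50 ± 0.095 and Cad, which starts pyrimidine synthesis, at -2.11 ± 0.085. Oxidative phosphorylation genes fell for 24 of 40 (camera adjusted p = 5.29e-07, adjusted p = 0.28 with an estimated correlation), such as Cox5a (-1.17 ± 0.056) and Cyc1 (-1.16 ± 0.054). TCA cycle genes fell for 13 of 24 (camera adjusted p = 0.000447, adjusted p = 0.208 with an estimated correlation), such as Dlat (-1.38 ± 0.048). Glycolysis genes fell for 10 of 22 and rose for 5 (camera adjusted p = 0.00127, adjusted p = 0.244 with an estimated correlation). Hk2, the first enzyme of the pathway, fell (-2.57 ± 0.068) and so did Ldha (-1.57 ± 0.05). Slc2a1, the glucose transporter, stood at 0.09 ± 0.063 (adjusted p = 0.196, edgeR) and Hif1a rose by 0.96 ± 0.083. Heat shock and folding genes fell for 13 of 19 and rose for 2 (camera adjusted p = 3.57e-08, adjusted p = 0.0639 with an estimated correlation), with Hspd1 at -2.42 ± 0.08 and Hspe1 at -2.24 ± 0.088.

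Of the cholesterol synthesis genes 22 of 24 were higher in TKO and 0 lower (camera adjusted p = 1.67e-10, adjusted p = 0.0877 with an estimated correlation), with Mvd at 2.17 ± 0.13 and Msmo1 at 2.12 ± 0.05. Of the unfolded protein response genes 17 of 23 rose (camera adjusted p = 5.09e-08, adjusted p = 0.229 with an estimated correlation), led by Xbp1 (from 57.3 ± 1.62 to 307 ± 12.8 CPM), Herpud1 (1.94 ± 0.061) and Ddit3 (1.94 ± 0.078). Of the interferon response genes 39 of 41 rose and 1 fell (camera adjusted p = 4.2e-10), with Ddx58, the RNA sensor RIG-I, at 4.89 ± 0.12 and Rsad2 at 3.95 ± 0.26. The amino acid supply and ATF4 target list split into 9 higher and 8 lower of 31 (camera adjusted p = 0.265), with the cystine transporter Slc7a11 at 6.00 ± 0.18 and Shmt1 at -3.34 ± 0.067. Cell cycle lists parted. G1/S genes fell for 22 of 42 and rose for 6 (camera adjusted p = 0.000474, adjusted p = 0.457 with an estimated correlation), with Ccnd2, the cyclin of early G1, at -3.11 ± 0.08. G2/M genes, which were near 0 in controls, rose for 25 of 30 (camera adjusted p = 0.000447, adjusted p = 0.181 with an estimated correlation). Mki67, the proliferation marker, lay at 1.58 ± 0.0621 CPM in controls and 31.7 ± 3.85 CPM in TKO. Markers of other cell types were also higher in these TKO libraries, and which cells held the G2/M transcripts was not tested.

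The Th17 program moved both ways, with 10 of 23 genes higher and 7 lower (camera adjusted p = 0.761). Il17a rose from 0.487 ± 0.0696 to 6.28 ± 0.564 CPM and Il17f from 1.97 ± 0.44 to 4.15 ± 0.567 CPM. By edgeR's glmTreat, which tests against the fold minimum, Il17f had an adjusted p of 0.078. Il22 rose from 0.147 ± 0.0204 to 1.96 ± 0.293 CPM and Il10, an inhibitory cytokine, from 0.463 ± 0.187 to 1.4 ± 0.381 CPM. Il21, which sustains Th17 cells, fell from 82.7 ± 12.1 to 9.1 ± 0.556 CPM and Ifng, the Th1 cytokine, from 15.1 ± 0.639 to 3.52 ± 0.652 CPM. Il23r (0.136 ± 0.107 and 0.398 ± 0.0911 CPM), Csf2 (1.07 ± 0.259 and 1.54 ± 0.589 CPM) and Rora (42.9 ± 2.89 and 47.1 ± 2.01 CPM) did not pass. Of the pathogenic Th17 signature 11 of 22 genes were lower and 7 higher (camera adjusted p = 0.0908), with the chemokine gene Ccl4 at -5.25 ± 0.14 and Tbx21, which encodes the Th1 factor T-bet, at -4.38 ± 0.23.

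The genes that rose most are known from other blood cells or were close to absent in controls. Ctla2b was at least 672-fold higher against a floor of 3 counts over the control group. The basophil and mast cell genes Prss34, Prg2, Ms4a2 and Mcpt8 lay at 42.7 ± 3.72, 10.5 ± 0.134, 10.1 ± 0.876 and 60.5 ± 5.26 CPM in TKO and at 0.0549 ± 0.0718, 0.0113 ± 0.0196, 0.009 ± 0.0156 and 0.126 ± 0.0318 CPM in controls. Epas1, a hypoxia-inducible factor, rose from 0.453 ± 0.143 to 176 ± 11.2 CPM. Summed myeloid and dendritic cell markers stood at 21.3 ± 1.27 CPM in controls and 340 ± 19.2 CPM in TKO (20 of 21 higher, camera adjusted p = 2.25e-10). Of those tested, 17 lay under 1 CPM in controls. Such genes can pass the filter through TKO libraries alone, which partly sets the counts of rises. Flt3, Siglech, Clec9a, Cd209a, C1qa, C1qc and Ms4a7 of that list, named after their values were seen, were not tested. Erythroid and platelet markers stood at 55.1 ± 5.59 and 1850 ± 144 CPM (11 of 12 higher, camera adjusted p = 4.2e-10) and B cell markers at 52.6 ± 2.16 and 376 ± 22.8 CPM (18 of 19 higher, camera adjusted p = 0.00016, adjusted p = 0.0742 with an estimated correlation). Of the CD8 and cytotoxic cell markers 8 of 14 rose and 4 fell (camera adjusted p = 0.82), while their sum, in which Xcl1 is the most abundant, stood at 442 ± 18.2 CPM in controls and 72.9 ± 2.51 CPM in TKO. The myeloid, erythroid and B cell sums were higher in the same libraries as the naive, trafficking, Treg and interferon genes and Il17a, Il17f and Il22. Which cells held the transcripts of these genes was not tested. The mitochondrially encoded share of counts was also higher there, at 4.018 ± 0.137% in TKO and 3.169 ± 0.114% in controls, whereas under TMM scaling 0 of 13 mitochondrially encoded genes rose and 0 fell (camera adjusted p = 0.958). More genes were detected in TKO (21910 ± 136 against 20880 ± 134), and predicted genes held 8.595 ± 0.165% of counts against 10.5 ± 0.251%. Each of these had an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. With library size scaling in place of TMM, the median of all genes moved by 0.23 on the log2 scale and 6019 genes rose and 3022 fell. Limma on CPM plus 1 and plus 0.0001 gave 4905 to 2519 and 5857 to 2973 for rises to falls. Counts adjusted over the list alone equalled those given for 33 of 35 lists, the others being the B cell markers and the non-pathogenic Th17 signature. The median, mean and test differed in sign for the Th17 program, the non-pathogenic Th17 signature and the amino acid list.

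**Figure D2:**
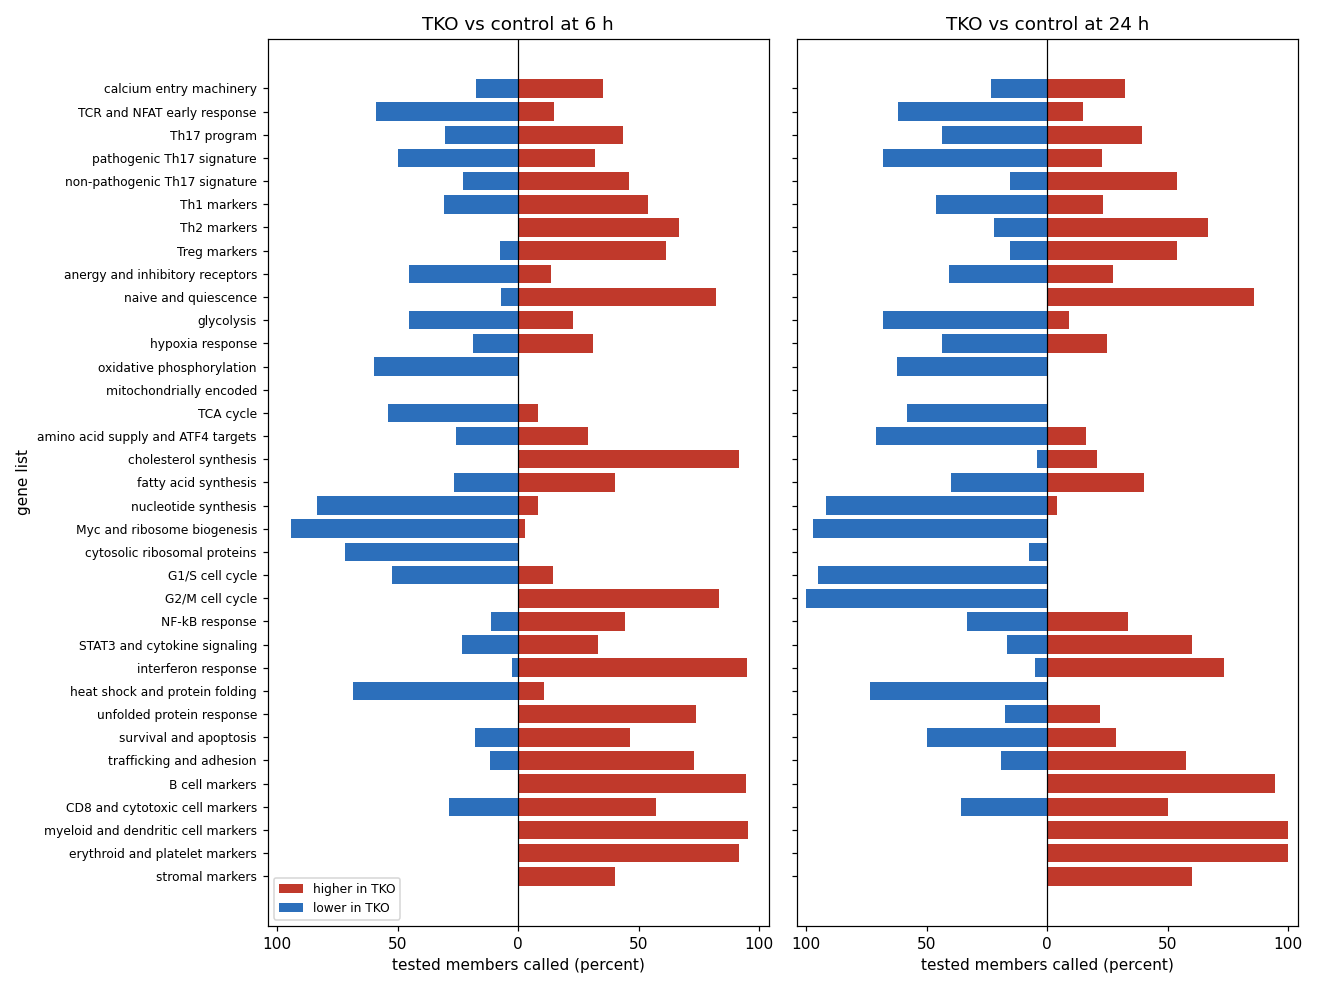
Percent of the tested members of each of 35 gene lists that rose (right of 0) or fell (left of 0) in TKO against control cells at 6 h and 24 h. Myc and ribosome biogenesis fell for 34 of 36 genes at 6 h and 35 of 36 at 24 h, whereas G2/M genes rose for 25 of 30 at 6 h and fell for 30 of 30 at 24 h.

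The comparison at 24 h asked how the genotypes differ at a later stage of activation. Proliferation genes were now lower in TKO cells. Mki67 stood at 996 ± 67.9 CPM in controls and 199 ± 22.3 CPM in TKO (-2.39 ± 0.089, adjusted p = 7.11e-12, edgeR). All 30 G2/M genes fell (camera adjusted p = 5.35e-27), led by Hmmr (-3.43 ± 0.13), Pbk (-3.23 ± 0.17) and the mitotic cyclin Ccnb1 (-3.10 ± 0.13). Of the G1/S genes 40 of 42 fell (camera adjusted p = 4.11e-23), led by Ccne2 (-3.14 ± 0.12), Rrm2 (-2.86 ± 0.12) and Mcm10 (-2.55 ± 0.11). Il2 was again lower, at 19.2 ± 2.23 against 692 ± 101 CPM (-5.24 ± 0.13). In all, 5063 genes rose in TKO and 4251 fell.

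The largest falls besides Xist were those of Tbx21 (-5.36 ± 0.25), Il2, Zbtb32 (-5.14 ± 0.26), Spin4 (-4.66 ± 0.18) and Xcl1 (-4.39 ± 0.24). T cell receptor and NFAT genes fell for 21 of 34 and rose for 5 (camera adjusted p = 1.94e-06, adjusted p = 0.104 with an estimated correlation). Il3 stood at 2.86 ± 1.15 CPM in controls and 0.0362 ± 0.0363 CPM in TKO, and Irf4 rose by 0.87 ± 0.053. Egr2 and Nr4a1 fell (-0.83 ± 0.084 and -0.64 ± 0.07), the latter under the fold minimum with library size scaling (-0.56). Of the naive and resting T cell genes 24 of 28 rose (camera adjusted p = 6.71e-23), with Klf2, a factor of quiescence, at 6.06 ± 0.23, Ypel3 at 5.13 ± 0.13 and Igfbp4 at 5.04 ± 0.10. Trafficking genes rose for 15 of 26 and fell for 5 (camera adjusted p = 9.8e-07), again with Ccr2 first (6.54 ± 0.16). Treg markers rose for 7 of 13 and fell for 2 (camera adjusted p = 0.00843), with Nt5e at 3.67 ± 0.17, Gpr83 at 2.38 ± 0.14 and Izumo1r at 2.18 ± 0.15. Genes of STAT3 and cytokine signaling rose for 18 of 30 and fell for 5 (camera adjusted p = 2.27e-06), with the decoy receptor Il1r2 at 3.14 ± 0.23, Socs3, a feedback inhibitor, at 2.92 ± 0.16 and Tgfbr2 at 2.51 ± 0.054. Interferon response genes rose for 30 of 41 and fell for 2 (camera adjusted p = 4.45e-08), including Gbp2 (3.58 ± 0.13) and Gbp5 (3.38 ± 0.093).

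Myc fell at 24 h too (-1.64 ± 0.062). Also 35 of 36 genes of its ribosome biogenesis list fell (camera adjusted p = 9.27e-31), with Srm at -2.84 ± 0.075 and Nolc1 at -2.12 ± 0.064. Nucleotide synthesis genes fell for 22 of 24 (camera adjusted p = 1.7e-14, adjusted p = 0.0566 with an estimated correlation), with Rrm2 and Dctpp1 (-2.61 ± 0.096) first. Amino acid supply and ATF4 target genes fell for 22 of 31 (camera adjusted p = 7.64e-09, adjusted p = 0.0938 with an estimated correlation), with Sesn2 at -2.46 ± 0.12 and Slc7a11 rising by 3.90 ± 0.22. Glycolysis genes fell for 15 of 22 (camera adjusted p = 2.58e-07, adjusted p = 0.0566 with an estimated correlation), with Hk2 at -2.32 ± 0.067 and Tpi1 at -1.86 ± 0.12. Slc2a1 fell (-0.65 ± 0.064), a call lost with library size scaling (-0.58), and Hif1a rose by 1.30 ± 0.084. Oxidative phosphorylation genes fell for 25 of 40 (camera adjusted p = 2.88e-09, adjusted p = 0.181 with an estimated correlation), with Cycs at -1.46 ± 0.051. TCA cycle genes fell for 14 of 24 (camera adjusted p = 2.85e-09), with Gls2 at -3.31 ± 0.22 and Dlat at -1.61 ± 0.049. Heat shock and folding genes fell for 14 of 19 (camera adjusted p = 5.29e-09), with Hspd1 at -2.64 ± 0.081 and Hsp90aa1 at -1.97 ± 0.058. Of the ribosomal proteins 3 of 39 fell (camera adjusted p = 0.562). Cholesterol synthesis genes rose for 5 of 24, a smaller share than the 5063 of 17184 over all genes. Their median log2 was 0.329 (camera adjusted p = 0.0453, adjusted p = 0.521 with an estimated correlation). Camera's adjusted p was 0.0618 without control replicate 1 at 6 h, 0.0597 without control replicate 2 at 6 h, 0.075 without TKO replicate 1 at 24 h and 0.0731 without TKO replicate 2 at 24 h. The unfolded protein response split into 5 higher and 4 lower of 23 (camera adjusted p = 0.796), with Ddit3 at 1.72 ± 0.084 and Atf3 at -1.09 ± 0.13. Survival and apoptosis genes were lower for 14 of 28 and higher for 8 (camera adjusted p = 0.0982), with the cell cycle inhibitor Cdkn1a at -3.27 ± 0.12 and Phlda3 at -3.02 ± 0.12.

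Of the pathogenic Th17 signature, 15 of 22 genes fell and 5 rose (camera adjusted p = 0.00519, adjusted p = 0.581 with members of only 1 list). Il1r1, the IL-1 receptor, stood at 30.6 ± 7.8 CPM in controls and 3.18 ± 2.31 CPM in TKO, and Ccl5 rose by 3.98 ± 0.23. The size of the Il1r1 fall depended on TKO replicate 3 at 24 h (log2 -4.1 without it). Of the non-pathogenic signature 7 of 13 rose and 2 fell (camera adjusted p = 0.0246, adjusted p = 0.181 with an estimated correlation, adjusted p = 0.188 with members of only 1 list), with Prdm1 at 3.98 ± 0.24, Cd5l at -3.20 ± 0.30, Ikzf3 at 3.06 ± 0.12 and Maf, which drives Il10, at 2.55 ± 0.12. The Th17 program as a whole split into 9 higher and 10 lower of 23 (camera adjusted p = 0.892). Il17f fell from 14.5 ± 3.32 to 1.2 ± 0.288 CPM (-3.65 ± 0.23), and Il21 (-2.28 ± 0.15), Rora (-0.93 ± 0.098) and Ifng (-3.22 ± 0.24) fell. Il23r fell from 5.72 ± 4.36 to 0.638 ± 0.298 CPM, and the size of its fall depended on control replicate 3 at 24 h (log2 -2.4 without it, adjusted p = 0.00045, edgeR). Il10 rose by 2.08 ± 0.40. Il17a lay at 1.23 ± 0.205 and 1.76 ± 0.367 CPM with a log2 fold change of 0.44 ± 0.21 (adjusted p = 0.0687, edgeR), which passed without TKO replicate 2 at 24 h (0.60). Il22 lay at 0.372 ± 0.151 and 0.794 ± 0.529 CPM and Csf2, the cytokine GM-CSF, at 1.42 ± 0.58 and 0.747 ± 0.263 CPM. Both depended on single libraries. For Il22 the adjusted p was 0.0533, and edgeR gave 0.0424 (log2 1.29) without control replicate 1 at 24 h, 0.537 (log2 0.29) without TKO replicate 1 at 24 h, 0.0271 (log2 1.25) without TKO replicate 2 at 24 h and 0.013 (log2 1.29) without TKO replicate 3 at 24 h. For Csf2 it was 0.0309, and edgeR gave 0.0594 (log2 -1.0) without control replicate 1 at 24 h, 0.17 (log2 -0.66) without control replicate 2 at 24 h, 0.0821 (log2 -0.91) without TKO replicate 2 at 24 h and 0.0777 (log2 -0.81) without TKO replicate 3 at 24 h. Of the calcium entry genes 11 of 34 rose and 8 fell (camera adjusted p = 0.453), with Stim1 at 0.78 ± 0.07 and Stim2 at 0.51 ± 0.043, under the fold minimum.

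Genes known from other blood cells were again higher in TKO. Cpa3, a mast cell protease, and Ltf, a neutrophil granule protein, were at least 426-fold and at least 343-fold higher against a floor of 3 counts over the control group. The globin genes Hba-a1, Hbb-bt, Hba-a2 and Hbb-bs lay at 102 ± 13.8, 54.3 ± 4.03, 201 ± 18.3 and 351 ± 23.9 CPM in TKO and at 0.0484 ± 0.0838, 0.0242 ± 0.0419, 0.151 ± 0.233 and 0.303 ± 0.344 CPM in controls. Summed markers stood at 18.7 ± 1.94 CPM in controls and 209 ± 22.6 CPM in TKO for myeloid and dendritic cells (21 of 21 higher, camera adjusted p = 2.3e-10). They stood at 2.12 ± 0.65 and 732 ± 61.2 CPM for erythroid cells and platelets (12 of 12, camera adjusted p = 1.62e-12). B cell markers stood at 100 ± 4.73 and 461 ± 22.6 CPM (18 of 19, camera adjusted p = 6.46e-06). As at 6 h, markers near absent in controls can pass the filter through TKO libraries alone, which partly sets these counts of rises. The 3 marker sums were higher in the same libraries as the naive, trafficking, Treg, STAT3 and interferon genes, and which cells held the latter was not tested. The mitochondrially encoded share was 3.651 ± 0.105% in TKO and 3.143 ± 0.108% in controls, genes detected were 21980 ± 603 and 20870 ± 71.3, and predicted genes held 9.355 ± 0.334% and 10.23 ± 0.112% of counts (exact permutation p of 0.1 for each). Under TMM scaling 0 of 13 mitochondrially encoded genes rose and 0 fell (camera adjusted p = 0.755). TKO replicate 3 at 24 h also held transcripts of skin, hair and muscle, at 3169 CPM summed over 50 markers, listed after such transcripts were seen there, against at most 117 CPM in any other library. Without it 4883 genes rose and 4466 fell. Counts adjusted over the list alone equalled those given for 33 of 35 lists, the others being the Th17 program and its pathogenic signature. The median, mean and test differed in sign for the Th17 program, anergy and inhibitory receptors, fatty acid synthesis and the unfolded protein response.

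**Figure D3:**
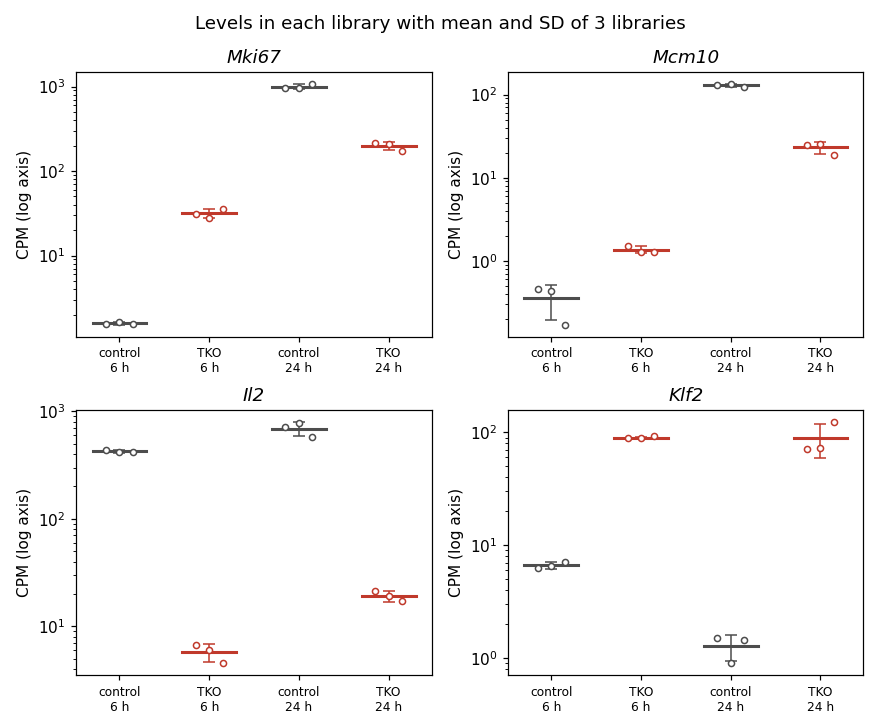
CPM of Mki67, Mcm10, Il2 and Klf2 in each library (points, log axis) with the mean (bar) and SD (whiskers) of 3 libraries per group. Mki67 lay at 1.58 and 31.7 CPM in control and TKO cells at 6 h and at 996 and 199 CPM at 24 h.

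The change from 6 h to 24 h in control cells served as the reference course of activation. Cell cycle genes rose in control cells. All 30 G2/M genes rose (camera adjusted p = 1.61e-104), Mki67 by 9.10 ± 0.14 on the log2 scale and the spindle checkpoint kinase Bub1 by 10.54 ± 0.21. Of the G1/S genes 38 of 42 rose and 2 fell (camera adjusted p = 1.46e-62), with Mcm10 at 8.26 ± 0.18 and Rrm2 at 7.57 ± 0.17. Early response genes declined, 21 of 34 in the T cell receptor and NFAT list (camera adjusted p = 5.23e-10, adjusted p = 0.132 with an estimated correlation), with Xcl1 at -3.51 ± 0.16, Nr4a3 at -2.47 ± 0.088 and Nr4a1 at -2.45 ± 0.07. In all, 3875 genes rose and 3568 fell (edgeR). The largest rises outside the lists were Depdc1a, from 0 ± 0 to 14.3 ± 1.43 CPM, and Neil3, from 0.00949 ± 0.0164 to 17.9 ± 1.77 CPM. Esco2 rose from 0.0659 ± 0.06 to 89.7 ± 9.9 CPM. These genes act in DNA repair or cell division. The largest falls were those of the globins Hbb-bs (from 26.3 ± 2.4 to 0.303 ± 0.344 CPM) and Hba-a2 (from 12.6 ± 2.26 to 0.151 ± 0.233 CPM), Tnnt2 (-5.84 ± 0.17) and Map1b (-4.11 ± 0.35). Erythroid and platelet markers fell for 10 of 12 (camera adjusted p = 1.81e-05, adjusted p = 0.152 with an estimated correlation).

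Glycolysis genes rose for 13 of 22 (camera adjusted p = 0.000227, adjusted p = 0.343 with an estimated correlation), with Tpi1 at 2.36 ± 0.12 and Slc16a3, a lactate exporter, at 2.10 ± 0.15. TCA cycle genes rose for 6 of 24 (camera adjusted p = 0.004, adjusted p = 0.4 with an estimated correlation), with Gls2 at 4.30 ± 0.24. Over all genes 3875 of 17184 rose, a share near that of the TCA cycle genes. Nucleotide synthesis genes rose for 7 of 24 (camera adjusted p = 0.0111, adjusted p = 0.593 with an estimated correlation, adjusted p = 0.829 with members of only 1 list), with Tyms at 4.33 ± 0.11. Of the survival and apoptosis genes 17 of 28 rose and 4 fell (camera adjusted p = 0.00546, adjusted p = 0.343 with an estimated correlation, adjusted p = 0.0739 with members of only 1 list), with Birc5, which also acts in mitosis, at 7.22 ± 0.21 and the death activator Bcl2l11 at -3.02 ± 0.078. Myc fell (-1.81 ± 0.061), and so did 20 of 36 ribosome biogenesis genes (camera adjusted p = 5.52e-09, adjusted p = 0.4 with an estimated correlation), such as Rrp9 (-1.29 ± 0.08). Ribosomal proteins fell for 12 of 39 (camera adjusted p = 0.000395, adjusted p = 0.593 with an estimated correlation), such as Rpl10a (-1.13 ± 0.073). NF-kB response genes fell for 16 of 27 (camera adjusted p = 5.78e-08, adjusted p = 0.152 with an estimated correlation), with Ltb at -2.73 ± 0.065 and Tnf at -2.12 ± 0.077. Of the non-pathogenic Th17 signature 8 of 13 fell and 3 rose (camera adjusted p = 0.0189, adjusted p = 0.343 with an estimated correlation, adjusted p = 0.637 with members of only 1 list), with Cd5l at 5.26 ± 0.36 and Maf at 64 ± 8.91 and 11.2 ± 2.22 CPM at 6 h and 24 h. Amino acid supply genes fell for 10 of 31 and rose for 3 (camera adjusted p = 0.0485, adjusted p = 0.593 with an estimated correlation, adjusted p = 0.0784 with members of only 1 list), with Sesn2 at 2.25 ± 0.12 and Slc3a2 at -1.45 ± 0.051. Camera's adjusted p was 0.0793 without control replicate 1 at 6 h, 0.0526 without control replicate 3 at 24 h, 0.0765 without TKO replicate 1 at 24 h and 0.06 without TKO replicate 3 at 24 h. Th17 genes split into 10 higher and 6 lower of 23 (camera adjusted p = 0.984). Ccr6, the chemokine receptor of Th17 cells, rose by 5.56 ± 0.32. Il17f rose from 1.97 ± 0.44 to 14.5 ± 3.32 CPM and Il23r from 0.136 ± 0.107 to 5.72 ± 4.36 CPM. The log2 change of Il23r was 5.99 without control replicate 1 at 6 h and 4.33 without control replicate 3 at 24 h. Orai1 fell (-1.24 ± 0.096) and Stim1 rose by 1.85 ± 0.076. With library size scaling the median gene moved by 0.19 and 4693 genes rose and 2519 fell. Limma on CPM plus 1 and plus 0.0001 gave 3847 to 1699 and 4633 to 2553 for rises to falls. Counts adjusted over the list alone equalled those given for 34 of 35 lists, the other being survival and apoptosis. The median, mean and test differed in sign for the Th17, Th1, Th2 and Treg lists, naive genes, trafficking and STAT3 signaling.

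In TKO cells the same interval asked how much of that course remains in the knockout. Cell cycle genes rose here too, 38 of 42 in the G1/S list (camera adjusted p = 2.69e-59), with Mcm10 at 4.05 ± 0.16 and Orc1 at 3.92 ± 0.19. In the G2/M list 27 of 30 rose (camera adjusted p = 8.97e-38), with Aurkb at 3.35 ± 0.17, Bub1 at 3.26 ± 0.14 and Mki67 at 2.62 ± 0.095. These rises start from the G2/M level in TKO at 6 h, whose cells of origin were not tested. Of the unfolded protein response genes 19 of 23 fell (camera adjusted p = 7.69e-38), with Atf3 at -3.74 ± 0.12, Creld2 at -2.15 ± 0.085 and Hspa5, the chaperone BiP, at -1.39 ± 0.062. Of the amino acid supply and ATF4 targets 25 of 31 fell (camera adjusted p = 5.48e-32), with Pycr1 at -3.44 ± 0.31 and Slc7a11 at -3.27 ± 0.14. In all, 2479 genes rose and 1751 fell (edgeR).

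Cholesterol synthesis genes fell for 15 of 24 (camera adjusted p = 4.01e-14), with Hmgcs1 at -1.52 ± 0.071. The NF-kB response fell for 18 of 27 genes (camera adjusted p = 5.43e-17), with Gadd45b at -2.85 ± 0.086. The T cell receptor and NFAT list fell for 19 of 34 (camera adjusted p = 9.25e-17), with Nr4a2 at -4.81 ± 0.14, Fosb at -4.50 ± 0.17 and Nr4a1 at -3.65 ± 0.074. Th1 markers fell for 7 of 13 (camera adjusted p = 0.000851), with Fasl at -2.26 ± 0.19 and Ifng at -2.02 ± 0.25. Ribosome biogenesis genes fell for 12 of 36 (camera adjusted p = 3.79e-11, adjusted p = 0.211 with an estimated correlation), with Odc1 at -2.48 ± 0.092. Heat shock genes fell for 2 of 19 (camera adjusted p = 0.00562, adjusted p = 0.315 with an estimated correlation), a share near the 1751 of 17184 over all genes. Genes of STAT3 and cytokine signaling rose for 11 of 30 and fell for 3 (camera adjusted p = 2.5e-05, adjusted p = 0.0695 with members of only 1 list), led by Socs2 (6.15 ± 0.47) and Il12rb1 (3.41 ± 0.093). Naive and resting genes rose for 11 of 28 and fell for 6 (camera adjusted p = 0.00423, adjusted p = 0.231 with an estimated correlation), with Igfbp4 at 4.93 ± 0.10. Glycolysis genes rose for 7 of 22 (camera adjusted p = 0.00629, adjusted p = 0.332 with an estimated correlation), with Pfkm at 1.68 ± 0.14. Nucleotide synthesis genes rose for 6 of 24 (camera adjusted p = 0.00479, adjusted p = 0.533 with an estimated correlation, adjusted p = 0.827 with members of only 1 list). Of the ribosomal proteins 1 of 39 passed, and the list lay above other genes (camera adjusted p = 0.00239, adjusted p = 0.549 with an estimated correlation). Il2 and Il21 rose by 1.71 ± 0.15 and 1.47 ± 0.17. Il17a and Il17f fell (-1.86 ± 0.19 and -1.81 ± 0.23), and Myc stood at -0.43 ± 0.061, under the fold minimum.

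Ramp3 (-5.80 ± 0.15), A1cf (-5.46 ± 0.29) and Tnnt2 (-5.46 ± 0.14) fell most besides Nr4a2. Of the genes that rose most, Cyp1a1, a target of the aryl hydrocarbon receptor, went from 0.222 ± 0.205 to 11.8 ± 1.35 CPM. Col1a1 had a log2 fold change of 8.79 ± 2.15 and Gja1 of 5.46 ± 1.32, and without TKO replicate 3 at 24 h these were 1.11 (adjusted p = 0.356, edgeR) and 1.22. Erythroid and platelet genes fell for 8 of 12 (camera adjusted p = 1.88e-06), and B cell markers rose for 5 and fell for 4 of 19 (camera adjusted p = 0.585). Myeloid and dendritic genes fell for 10 of 21 (camera adjusted p = 0.00479, adjusted p = 0.211 with an estimated correlation), and CD8 and cytotoxic genes for 5 of 14 (camera adjusted p = 0.042, adjusted p = 0.129 with an estimated correlation, adjusted p = 0.108 with members of only 1 list). For the last list camera's adjusted p was 0.0505 without control replicate 3 at 24 h and 0.0634 without TKO replicate 3 at 6 h. The mitochondrially encoded share stood at 4.018 ± 0.137% at 6 h and 3.651 ± 0.105% at 24 h, and 0 of the 13 genes fell (camera adjusted p = 0.135). Without TKO replicate 3 at 24 h 2308 genes rose and 1974 fell. Counts adjusted over the list alone equalled those given for 32 of 35 lists, the others being calcium entry, the non-pathogenic Th17 signature and the interferon response. The median, mean and test differed in sign for the non-pathogenic Th17 signature, hypoxia, the TCA cycle and the interferon response.

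The interaction asked whether the genotype difference changed between 6 h and 24 h, and a negative value means that TKO cells stood lower relative to controls at 24 h than at 6 h. All 30 G2/M genes shifted down (camera adjusted p = 1.52e-67), Mki67 to -6.48 ± 0.17 and Bub1 to -7.28 ± 0.35. Of the G1/S genes 28 of 42 did (camera adjusted p = 5.34e-13, adjusted p = 0.21 with an estimated correlation), with Mcm10 at -4.21 ± 0.31 and Rrm2 at -3.84 ± 0.25. The G2/M shift includes the higher level in TKO at 6 h, whose cells of origin were not tested. Maf, Ahr and Ikzf3 of the non-pathogenic Th17 signature shifted up by 4.37 ± 0.17, 3.37 ± 0.11 and 2.78 ± 0.16, and Cd5l shifted down to -4.41 ± 0.52 (camera adjusted p = 2.69e-06, adjusted p = 0.278 with members of only 1 list). Of the Th1 markers 8 of 13 shifted down (camera adjusted p = 2.49e-05), led by the IL-18 receptor genes Il18r1 (-4.35 ± 0.34) and Il18rap (-4.35 ± 0.36) and by Il12rb2 (-4.01 ± 0.18). The interaction was called for 2586 genes upward and 2904 downward (edgeR).

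Downward shifts also met 15 of 23 unfolded protein response genes (camera adjusted p = 2.36e-13, adjusted p = 0.149 with an estimated correlation), with Sdf2l1 at -2.54 ± 0.12. Amino acid supply genes shifted down for 20 of 31 (camera adjusted p = 4.72e-10, adjusted p = 0.144 with an estimated correlation), with Sesn2 at -3.15 ± 0.17. Cholesterol synthesis genes did for 17 of 24 (camera adjusted p = 2.37e-11, adjusted p = 0.105 with an estimated correlation), with Pmvk at -1.67 ± 0.15. Survival genes did for 18 of 28 (camera adjusted p = 6.62e-06, adjusted p = 0.102 with an estimated correlation), with Birc5 at -4.30 ± 0.33 and Cdkn1a at -3.63 ± 0.17. Ribosomal proteins shifted up for 22 of 39 (camera adjusted p = 2.12e-12, adjusted p = 0.282 with an estimated correlation), with Rpl37 at 1.41 ± 0.19 and Rps18 at 1.11 ± 0.089. Other upward shifts were those of Tox2 (5.42 ± 0.25) and Igfbp4 (4.66 ± 0.14). Iqgap3, which acts in cell division, shifted down to -7.29 ± 0.44. Depdc1a lay at 0 ± 0 and 0.438 ± 0.0796 CPM in controls and TKO at 6 h and at 14.3 ± 1.43 and 2.83 ± 0.187 CPM at 24 h. The globins Hba-a1 and Hbb-bs moved with the erythroid list (7 of 12 up, camera adjusted p = 0.000128, adjusted p = 0.142 with an estimated correlation), at 7.22 ± 1.55 and 272 ± 31.8 CPM at 6 h and 0.0484 ± 0.0838 and 102 ± 13.8 CPM at 24 h for Hba-a1.

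Among cytokine genes, Il2 and Il21 shifted up by 1.19 ± 0.18 and 1.13 ± 0.21, and Il17a and Il17f shifted down to -3.00 ± 0.30 and -4.51 ± 0.31. Which cells held Il17a and Il17f in TKO at 6 h was not tested. Myc and Egr2 shifted up by 1.38 ± 0.086 and 0.84 ± 0.12, as did Stim2 (0.75 ± 0.06). Stim1, Nr4a1, Rora and Slc2a1 shifted to -1.0 ± 0.10, -1.20 ± 0.096, -0.83 ± 0.14 and -0.74 ± 0.09. Hk2 (0.25 ± 0.093) and Hif1a (0.34 ± 0.12) stayed under the fold minimum. Orai1 stood at 0.65 ± 0.19, a call that ended without control replicate 1 at 6 h (0.52), TKO replicate 3 at 6 h (0.56) and TKO replicate 3 at 24 h (0.44) and with library size scaling (0.49). Ifng stood at -0.88 ± 0.31, and edgeR gave adjusted p values of 0.0505 (log2 -0.89) without control replicate 3 at 6 h, 0.0723 (log2 -0.76) without control replicate 1 at 24 h, 0.0708 (log2 -0.75) without control replicate 2 at 24 h, 0.0788 (log2 -0.73) without TKO replicate 1 at 6 h and 0.0874 (log2 -0.76) without TKO replicate 2 at 24 h. Il22 stood at -2.45 ± 0.66 and Il23r at -4.48 ± 0.90. Both stayed called when any 1 library was left out, with values of -3.20 without TKO replicate 1 at 24 h and -5.33 without control replicate 1 at 6 h and -3.67 without control replicate 3 at 24 h. Between the times, 3283 genes rose and 2700 fell in TKO at both, against 1468 and 1038 for independent lists. The odds ratios were 11.3 (95% interval 10.5 to 12.2) and 13.3 (12.3 to 14.5) by Fisher's exact test, whose intervals treat genes as independent and leave out the spread between mice. The comparisons share no libraries, although the cells of 1 genotype may come from 1 pool. The direction turned for 342 genes that were higher in TKO at 6 h and lower at 24 h and for 99 that went the other way, with the interaction called for each. Across 17184 genes, which are not independent replicates, the time change in TKO cells had Pearson's r of 0.535 and Spearman's rho of 0.488 with that in controls, with a least-squares slope of 0.338 (Deming 0.449). The change was smaller in TKO for 11738 genes (68.3%). With library size scaling the median interaction moved by -0.15. That scaling gave 1832 to 3548 genes, and limma on CPM plus 1 and plus 0.0001 gave 1538 to 3342 and 1713 to 3501 for shifts up to shifts down. Counts adjusted over the list alone equalled those given for 29 of 35 lists, the others being the T cell receptor, Th17, pathogenic Th17, Th2, STAT3 and B cell lists. The median, mean and test differed in sign for the Th17 program, CD8 and stromal markers.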

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

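None of the tests in this part was chosen only after its result was seen. What set these results apart is that the interaction test found a genotype difference at 24 h unlike that at 6 h, with 2586 genes shifting up and 2904 shifting down in TKO relative to control. Of the 16 lists whose shift passed camera's test, those moving down with time were led by G2/M genes (camera adjusted p = 1.52e-67), the unfolded protein response (2.36e-13), G1/S genes (5.34e-13), cholesterol synthesis (2.37e-11) and amino acid supply (4.72e-10). The others moving down were survival and apoptosis (6.62e-06), Th1 markers (2.49e-05), the TCA cycle (0.00334), glycolysis (0.0234) and fatty acid synthesis (0.0234). Those moving up were ribosomal proteins (camera adjusted p = 2.12e-12), the non-pathogenic Th17 signature (2.69e-06), erythroid and platelet markers (0.000128), STAT3 signaling (0.000174), naive genes (0.00286) and anergy genes (0.0446). Only the G2/M, non-pathogenic Th17 and Th1 lists held with an estimated correlation, and of these the non-pathogenic Th17 list was not called with members of only 1 list (0.278). The anergy list had adjusted p values of 0.0823 without control replicate 1 at 6 h, 0.0595 without control replicate 2 at 6 h, 0.0882 without control replicate 3 at 24 h, 0.0731 without TKO replicate 1 at 6 h and 0.0674 without TKO replicate 1 at 24 h by camera.

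Per gene, the shift on the log2 scale was -7.28 for Bub1, -7.29 for Iqgap3, -6.48 for Mki67, -4.21 for Mcm10, -3.84 for Rrm2 and -4.30 for Birc5, all genes of dividing cells. Which cells held such transcripts in the TKO libraries at 6 h was not tested. Of the cytokine genes named, Il17f stood at -4.51, Il17a at -3.00, Il22 at -2.45 and Ifng at -0.88, and Il2 at 1.19 and Il21 at 1.13. Il23r stood at -4.48, Il18r1 at -4.35, Il18rap at -4.35 and Il12rb2 at -4.01. Leaving out 1 library ended the call for Ifng (edgeR adjusted p of 0.0505 (log2 -0.89) without control replicate 3 at 6 h, 0.0723 (log2 -0.76) without control replicate 1 at 24 h, 0.0708 (log2 -0.75) without control replicate 2 at 24 h, 0.0788 (log2 -0.73) without TKO replicate 1 at 6 h and 0.0874 (log2 -0.76) without TKO replicate 2 at 24 h). It moved Il22 to -3.20 without TKO replicate 1 at 24 h. Il23r moved to -5.33 without control replicate 1 at 6 h and -3.67 without control replicate 3 at 24 h. Maf stood at 4.37, Ahr at 3.37, Ikzf3 at 2.78, Tox2 at 5.42, Myc at 1.38 and Egr2 at 0.84, Nr4a1 at -1.20 and Rora at -0.83. Of the calcium entry genes, Orai1 stood at 0.65, a call that ended without control replicate 1 at 6 h (0.52), TKO replicate 3 at 6 h (0.56) and TKO replicate 3 at 24 h (0.44). Stim1 stood at -1.0 and Stim2 at 0.75. Metabolic and stress genes stood at -2.54 (Sdf2l1), -3.15 (Sesn2), -1.67 (Pmvk), -0.74 (Slc2a1) and -3.63 (Cdkn1a). Ribosomal proteins stood at 1.41 (Rpl37) and 1.11 (Rps18), and Cd5l and Igfbp4 at -4.41 and 4.66.

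The interaction was refitted with labels regrouped at both times. Of 100 regroupings drawn from 200, 5 called as many genes as the real labels or more, the real ones included. The real labels called 5490 genes and the highest other regrouping 6380. The other 4 that reached the real count kept all 6 labels at 6 h and 2 of 6 at 24 h, which turns a genotype difference shared by both times into an interaction. Each regrouping with a called gene kept all or none of the labels at 6 h or at 24 h. The count therefore follows from how the labels were regrouped and says nothing on chance.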

How the results depend on the processing

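Of the settings in this part, only the fit without genes of the X and Y chromosomes, of other cell types and of skin was chosen after the data were seen. It gave 4754 to 4039 genes for rises to falls at 6 h, 4859 to 4087 at 24 h, 3705 to 3457 over time in control, 2383 to 1676 over time in TKO and 2498 to 2783 for the interaction. A filter of 10 CPM in 3 libraries tested fewer genes, 9881, and gave 2822 to 2434 at 6 h, 2598 to 2681 at 24 h, 2245 to 1720 in control, 1301 to 996 in TKO and 1338 upward shifts in the interaction. Limma on CPM plus 1 gave 2519 falls at 6 h, 1699 falls in control over time and 1538 upward shifts. On CPM plus 0.0001 it gave 1713 upward shifts. These CPM are scaled by library totals, and library size scaling in edgeR gave 3022 falls at 6 h, 2519 in control and 1832 upward shifts, with a median interaction moved by -0.154, against -0.156 for limma on CPM plus 0.0001. What lowered the counts further with plus 1 was not tested. By construction, a fold minimum of 2 left 2436 falls at 6 h, 2662 at 24 h, 2010 in control, 1446 rises and 913 falls in TKO and 1419 upward shifts. No fold minimum gave 6160 falls in control, 4538 rises and 4203 falls in TKO and 4374 upward shifts. GlmTreat gave 1329 rises and 993 falls in TKO and 1310 upward shifts. Genes falling at both times numbered 4366 with no fold minimum and 1431 with a minimum of 2. The slope of the TKO on the control time change was 0.374 over genes with 10 CPM in 3 libraries and 0.353 over genes called in either genotype.

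Leaving out 1 library at a time gave 4869 to 5234 up and 3870 to 4380 down at 6 h, and 4883 to 5250 up and 4130 to 4466 down at 24 h. It gave 3799 to 4119 up and 3127 to 3735 down in control, 2216 to 2641 up and 1606 to 1974 down in TKO and 2123 to 2582 up and 2767 to 3203 down for the interaction. Lists called ranged over 19 to 22, 20 to 22, 12 to 14, 17 to 19 and 15 to 17 in the same order. Genes rising at both times ranged over 3210 to 3369, genes falling at both over 2602 to 2746, and the slope over 0.305 to 0.35. Camera called 19, 21, 13, 18 and 16 lists in these comparisons, and with an estimated correlation 7, 14, 2, 10 and 3 of them held. For 47 of the 51 calls that ended, that p was the highest over all alternatives. Fry, which asks only whether genes of a list move one way, called 34, 30, 29, 33 and 27. With members of only 1 list, the non-pathogenic Th17 signature was no longer called at 24 h (0.188), over time in control (0.637) or in the interaction (0.278), nor was the pathogenic signature at 24 h (0.581, camera adjusted p). The same setting ended the calls of nucleotide synthesis (0.829), survival (0.0739) and amino acid supply (0.0784) in control over time. In TKO over time it ended those of nucleotide synthesis (0.827), STAT3 signaling (0.0695) and CD8 markers (0.108). This setting also added calls, 2 at 6 h (NF-kB response and STAT3 signaling, camera adjusted p = 0.044 each), 1 in TKO over time and 2 in the interaction. Replicate numbers were not taken to pair the libraries, which would have needed a correlation over 0.1 in every pair with the same number. Deviations from the group mean reached it in 7 of 18 such pairs, with a median of 0.0741 against -0.0552 for other numbers. As a hint of pairing from the data, 8 of 12 libraries correlated best with their own number. The replicate block gave 5001 to 4199, 5028 to 4282, 3874 to 3570, 2420 to 1773 and 2562 to 2939, in the same order. The block also ended the calls of amino acid supply in control over time (camera adjusted p = 0.0517), of CD8 markers in TKO over time (0.0581) and of anergy genes in the interaction (0.0697), and no other list call. Of the 234 calls of named genes, 20 ended under some alternative, 9 of them under another tool, scaling, filter or library choice and the others only under glmTreat or a fold minimum of 2. Of the other changes of named genes 11 were called under some alternative, and 0 reversed. Depth limits genes near 3 counts over a group. Simulated changes of 1.5-fold, equal to the fold minimum, were called for 41, 42, 31, 35 and 28 of 73 genes in the 5 comparisons and passed the adjusted p alone for 71, 69, 64, 68 and 59.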

Other observations

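The tests on Y-linked genes, on general T cell genes, on markers of other cell types and on skin transcripts were chosen only after the result was seen, and those on X-linked genes, escape genes, the Orai regions and regrouped samples before. Genes that mark T cells in general were mostly higher in TKO cells. Of 24 such genes 13 rose and 3 fell at 6 h, and 16 rose and 2 fell at 24 h (edgeR). Skap1, a T cell receptor adaptor, had log2 fold changes of 2.90 and 1.93 at 6 h and 24 h, and Tcf7, a factor of naive and memory T cells, of 1.79 and 1.56. Cd4 had 1.54 and 0.98 and Cd3g 1.28 and 1.98. Trac, the constant part of the receptor alpha chain, fell to -1.28 and -0.96 and Zap70, a proximal kinase, stood at -1.40 and -0.33. These genes were named after their values were seen.

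Lists of inhibitory receptors and fatty acid synthesis went both ways. Of 22 anergy and inhibitory receptor genes 10 fell and 3 rose at 6 h (camera adjusted p = 0.0606), and 9 fell and 6 rose at 24 h (0.65). Pdcd1, which encodes the checkpoint receptor PD-1, fell to -4.85 ± 0.12 and -4.36 ± 0.12 on the log2 scale at 6 h and 24 h. Lag3 fell to -3.11 ± 0.095 at 6 h, and Dgka, which dampens receptor signals by consuming diacylglycerol, rose by 4.13 ± 0.076 at 6 h. Of 15 fatty acid synthesis genes 6 rose and 4 fell at 6 h (camera adjusted p = 0.396), with the desaturase Scd2 at 3.09 ± 0.16 and Fasn at -0.93 ± 0.051. Of 16 hypoxia response genes 5 rose and 3 fell at 6 h (camera adjusted p = 0.702), with Egln3 at -2.64 ± 0.11 and Bnip3l at 2.08 ± 0.081. Th2 markers rose for 6 of 9 (camera adjusted p = 0.0858), among them Il1rl1, also made by basophils and mast cells, at 5.61 ± 0.35.

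The first pattern is the near absence of Xist from TKO libraries that carry the label female. A pair of active X chromosomes is argued against, since X-linked genes stood -0.0952 from autosomal genes at 6 h and -0.194 at 24 h (median log2), where a rise is needed. A single X chromosome could account for the lack of Xist. Genes that escape inactivation stood -1.03 and -1.15 from autosomal genes (permutation p = 0.0442 and 0.0257, 10000 permutations, which treat genes as independent). Of these 8 genes 5 fell and 0 rose at each time. If controls hold male cells too, the loss of a copy would give a smaller fall, so the size of this fall is not accounted for. The sum of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty reached 494 CPM in TKO, and the first bound set for male cells, under 0.5 CPM in controls, was wrong because controls also carry these transcripts at 40.3% and 34.9% of the TKO level (73.9% and 51.7% over all 15 Y chromosome genes of the table). A candidate explanation is therefore male cells in the TKO pools and cells of both sexes in the control pools, with the lowest TKO sum of the 4 genes 1.96 times the highest control sum (1.2 over all Y chromosome genes, of which, among those over 1 CPM, Gm47283 and Mid1-ps1, named after their values were seen, stood higher in controls, at 162 and 7.65 CPM against 104 and 1.61, and are not accounted for), so that sex would be confounded with genotype in each comparison of TKO with control and in the interaction, for every gene and not only X- and Y-linked ones.

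The second pattern is the rise of markers of other cell types beside the fall of activation genes, where 4 of 21 myeloid, 6 of 12 erythroid and 7 of 19 B cell genes reached 1 CPM in controls at 6 h too. A lower share of T cell RNA that raised every other type alike would give equal rises. Myeloid markers rose by 2.23 more than B cell markers at 6 h (difference of medians on the log2 scale, permutation p = 0.00085, 100000 permutations, and 2.23 with 2 myeloid genes at their floor). Over the 17 myeloid and 12 B cell genes under 1 CPM in controls they rose by 2.5 more (permutation p = 0.00036, and 2.5 with 2 genes at their floor). These values argue against an equal rise only, and the permutations treat genes as independent. They leave a lower share with unlike rises of the other types undecided. Dilution of T cell RNA is argued against by the rise of general T cell genes, by a median of 0.624 at 6 h. More myeloid and erythroid cells left in the TKO pools after magnetic enrichment may remain, with at least 190 CPM of myeloid markers in each TKO library and Hbb-bs, Hba-a2 and S100a9 at 861 ± 61.3, 492 ± 37.8 and 63 ± 4.23 CPM at 6 h. Since the cells of each genotype were pooled, this cannot be told apart from an effect of genotype on the pool, which stays open and untested.

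The third pattern is the skin, hair and muscle signal in TKO replicate 3 at 24 h. Of 50 markers, listed after such transcripts were seen there, 45 (90%) lay at least 10-fold above every other library, and 503 genes stood over 2-fold above the mean of the other replicates of the group (CPM plus 1) against 10 below. RNA of such tissue in that library is a candidate explanation, but a list drawn up from the signal cannot test it. Lower depth alone is argued against, since the summed counts of these markers were 22.1 times the highest elsewhere. RNA quality is left undecided by a mitochondrial share of 3.541% within the range of the others and a total of 27525004 counts, the lowest of the 12, and no biological explanation was tested.

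Sequence carried along with the targeted alleles was looked for as a higher share of genes called alike at both times near Orai1, Orai2 and Orai3. Within 5 Mb 143 of 437 genes were called so against 5838 of 16744 elsewhere, a ratio of shares of 0.939 (Fisher's exact test p = 0.36). These values show no broad excess near the Orai genes. With 34.9% of genes elsewhere called alike, an effect on a few genes per locus could not be seen and stays undecided. Of the 10 splits of 6 libraries into 3 and 3, 1, the real one, gave as many called genes in each pairwise comparison, with 9177, 9314, 7443 and 4230 calls. The highest other split called 0 genes by edgeR, with at most 192, 697, 382 and 1097 genes at an unadjusted p under 0.05. These 10 splits are too few for a share under 0.05. Each other split also puts libraries of both groups on each side, which adds their difference to the spread. The 0 calls therefore follow from the regrouping and say nothing on chance.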
